A study of Mus musculus with 24 samples.

How the data were processed

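The samples were 24 Illumina bead arrays of mouse cells, 3 for each of 8 populations: common DC progenitors, total pre-DC and 4 pre-DC subsets from bone marrow, and CD8a+ and CD11b+ DC from spleen. Per the labels, total RNA of untreated primary cells of male C57BL/6 mice at steady state was extracted with the miRVana kit and checked on an Agilent Bioanalyzer. Also per the labels, biotin-labelled RNA was made with the Epicentre TargetAmp kit for Illumina arrays. The sources used here do not say whether the replicates of a population came from separate mice, how the cells were sorted, or which BeadChip held which array.

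The deposited table of non-normalized values holds, per the file headers, an average bead signal intensity for each of 45281 probes on each array, and no background correction or normalization is recorded for it. Beside each intensity the same deposited table holds, per the file headers, a detection p-value. The steps of 0.001068 between these p-values correspond to 936 negative control beads, a number found here from the values. The deposited processed intensity values were made with lumi per the labels, with its version not given in the sources used here. Their distributions, compared here, were the same for all 18 bone marrow arrays (median 81.8) and another for all 6 spleen arrays (median 152), as after quantile normalization in 2 separate sets. Columns were tied to samples by their names, and all 24 non-normalized columns had the same probe ranks as the processed column of their own sample (rank correlation of at least 0.9999, against at most 0.939 with any other sample). The deposited columns name the CD11b+ DC of spleen by CD4, and the sample titles name them by CD11b; the probe ranks tie the columns to the samples, and the titles' name was used.

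Gene symbols came from the GEO platform annotation: 34885 probes had 1 symbol, 18 had several and 10378 had none. Of 19074 gene IDs, 18992 were found in the reference gene table, and 0 symbols needed updating. Values were corrected for background and quantile normalized together with the neqc function of limma 3.58.1 (R 4.3.3), using the detection p-values and an offset of 16, and taken to log2. Of the 19057 genes with a probe, 9172 had more than 1, and the probe with the highest mean signal was used. Genes were tested where the detection p-value was under 0.05 on all 3 arrays of at least 1 population, which left 10317 genes, 6227 of them with more than 1 probe. Genes named by size, transcription factors and sorting markers were compared with their other detected probes, and 1 of 211 comparisons passed in the opposite direction. Genes named only as list members were not compared, and sizes could differ between probes.

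All 24 arrays entered 1 linear model with a mean per population (16 residual and 3.38 prior degrees of freedom), fitted with lmFit and eBayes. The 7 contrasts were total pre-DC against CDP, CD8a+ against CD11b+ splenic DC, Ly6C+ against Ly6C- pre-DC without and with Siglec-H, Siglec-H+ against Siglec-H- pre-DC, the interaction of Ly6C with Siglec-H, and splenic DC against total pre-DC. Adjusted p-values are those of the moderated t test of limma, adjusted by the Benjamini-Hochberg method over all genes of a contrast, with a threshold of 0.05. The 19 gene lists were written from general knowledge before any value was read: type 1 and type 2 conventional DC, plasmacytoid DC, MHC class II pathway, DC maturation, cell cycle, stem and progenitor, neutrophil and granule, monocyte, macrophage, B cell, T cell and NK cell, erythroid, basophil with mast cell and eosinophil, type I interferon response, immediate early and stress, Toll-like receptor, chemokine and homing receptor, and C-type lectin receptor genes. They were tested with camera of limma at a preset correlation between genes of 0.01, with p-values adjusted over all lists and contrasts together, and again with an estimated correlation. Genes named in the report were the 8 with the largest change each way that passed (5 for the interaction), the leading 3 list members each way, and transcription factors and sorting markers written down beforehand. For the agreement of contrasts, the arrays were regrouped in all paired ways; for the splenic score, an exact permutation test was used. The 2 score gene sets were tested with camera too, and adjusted over these tests alone.

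Arrays of Ly6C+Siglec-H- and Ly6C-Siglec-H- pre-DC with the same replicate number correlated in their deviations from their population mean, at 0.321, 0.226 and 0.478 in the data, and no other pair of populations set directly against each other here did so for all 3 numbers. The fit was tested on simulated data of 10317 genes, 200 of them changed. All genes changed by a log2 of 2 were recovered. For the interaction, 80.6% were recovered at a log2 of 1 and 32.8% at 0.5, with 8 unchanged genes among 150 calls. For the Siglec-H contrast the shares were 98.5% and 79.1%, with 14 unchanged genes among 199 calls. Ly6C without Siglec-H had the most unchanged genes, 16 among 178 calls, and total pre-DC against CDP had 15 among 178. The splenic subsets had the fewest, 5 among 173. The share of unchanged genes among calls thus lay above the threshold on the adjusted p-value in some of the simulated contrasts. Each contrast had a single random draw, with independent noise of the same spread on all arrays. Differences between contrasts in unchanged genes called therefore cannot be told from the scatter of the draws. Deviations shared by arrays with the same replicate number were not simulated.

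Alternatives covered background correction, normalization (median scaling, cyclic loess, the deposited processed values), the filter, the choice of probe, the arrays in the fit, the prior, array weights, thresholds, a replicate block, the list test, the size of the score and leaving out each array in turn. Another 3 were chosen after seeing the data: the mean of the 4 pre-DC subsets in place of total pre-DC in each of its 2 contrasts, and normalizing bone marrow and spleen separately. A block by BeadChip was not run. For the interaction, residuals of the additive fit of Ly6C and Siglec-H were also regrouped. Probes with no symbol or several were left out.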

Results

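Messenger RNA was measured on Illumina bead arrays in 8 dendritic cell (DC) populations of untreated male C57BL/6 mice at steady state. There were 3 arrays per population and 24 in all. Bone marrow gave 18 arrays: common DC progenitors (CDP), total pre-DC (the next stage of DC development), and 4 pre-DC subsets defined by the surface proteins Ly6C and Siglec-H. Spleen gave 6 arrays, of CD8a+ DC and CD11b+ DC, the mature conventional DC subsets of that organ. Median bead intensities lay between 67.1 and 103 on the bone marrow arrays and between 114 and 223 on the spleen arrays. Between 17584 and 18857 probes were detected per bone marrow array, and between 13104 and 16689 per spleen array. Over the 10317 genes tested, arrays of the same population correlated at r = 0.983 to 0.996. The number of arrays limits the precision of every value. Nothing in the sample labels says that the 3 replicates of a population came from separate mice, so the p-values measure only the spread between these samples. Levels are log2 intensities given with their SD (n = 3), and differences are log2 fold changes from limma given with their standard error (SE).

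The genes encoding the sorting markers followed the names of the populations where their probes gave signal. Siglech, a receptor gene of plasmacytoid DC, stood at 13.64 ± 0.16 in Ly6C+Siglec-H+ and 13.82 ± 0.11 in Ly6C-Siglec-H+ pre-DC. Without Siglec-H it stood at 10.84 ± 0.27 in Ly6C+Siglec-H- and 11.64 ± 0.31 in Ly6C-Siglec-H- pre-DC. Ly6c1 stood at 13.08 ± 0.07 and 12.39 ± 0.03 in the Ly6C+ subsets with and without Siglec-H. The matching Ly6C- subsets stood at 10.34 ± 0.08 and 8.83 ± 0.20. Total pre-DC held less Siglech mRNA (10.16 ± 0.10) than any of the 4 subsets, and CDP stood at 10.45 ± 0.28. Sirpa, a marker of CD11b+ DC, was higher in CD11b+ (13.61 ± 0.04) than in CD8a+ splenic DC (9.31 ± 0.41). Both Cd8a probes were below the detection limit on all arrays, CD8a+ DC included. The Itgam probe, for CD11b, was detected on 1 of 3 arrays of CD11b+ DC, so neither gene could check those labels.

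Total pre-DC were set against CDP to ask what changes from one progenitor stage to the next. Genes of antigen presentation rose in total pre-DC: Cd74, the invariant chain, by 3.19 ± 0.19 (adjusted p = 2.5e-11), H2-Eb1 by 2.83 ± 0.16 (adjusted p = 2.4e-11) and Ciita, the master regulator of MHC class II, by 2.67 ± 0.14 (adjusted p = 6.0e-12). The transcription factors Irf4 (3.22 ± 0.27), Klf4 (2.17 ± 0.17), Spib (2.05 ± 0.17) and Batf3 (1.35 ± 0.10) rose as well. Dntt, the terminal nucleotidyl transferase, fell by -4.55 ± 0.17 (adjusted p = 4.1e-14), and the progenitor genes Cd34 and Sox4 by -1.74 ± 0.17 and -2.30 ± 0.27. The genes with the largest rise were Vcam1 (6.99 ± 0.35, adjusted p = 2.3e-12), the iron exporter Slc40a1 (6.50 ± 0.39) and the ficolin Fcna (6.08 ± 0.26), all known from tissue macrophages. Irf8 (-0.25 ± 0.18, adjusted p = 0.28), Id2 (0.47 ± 0.20, adjusted p = 0.061; its other 2 probes passed, at 1.47 and 0.39), Tcf4 (-0.10 ± 0.21, adjusted p = 0.74) and Zeb2 (0.51 ± 0.24, adjusted p = 0.097) did not pass the test.

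By gene list, 11 of 14 measured MHC class II pathway genes rose and 1 fell (11 and 1 adjusted over the list alone; camera, adjusted p = 9.4e-08). Of 21 conventional DC type 2 genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone; adjusted p = 2.1e-06), led by the lectin genes Cd209a (4.00 ± 0.39) and Clec4a1 (3.32 ± 0.20). Of 21 stem and progenitor genes, 13 fell and 1 rose, with the same counts adjusted over the list alone (adjusted p = 9.3e-05). Of 24 type I interferon response genes, 14 rose and 1 fell, likewise over the list alone (adjusted p = 5.8e-06), among them Ifit3 (2.55 ± 0.13) and Irf7 (2.22 ± 0.09). The Toll-like receptors (9 of 15 up, 10 adjusted over the list alone; adjusted p = 7.1e-05) and the C-type lectin receptors (12 of 22 up, 14 adjusted over the list alone; adjusted p = 1.3e-05) rose too, with 1 member of each down. Conventional DC type 1 genes were up in 8 of 20 and down in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.0046), a call that was lost at adjusted p = 0.082 with an estimated correlation. Btla (2.44 ± 0.09) and Clec9a (1.67 ± 0.11) rose most among those measured on both sides. The 23 plasmacytoid DC genes (9 up, 6 down; adjusted p = 0.45) and the 34 cell cycle genes (6 up, 13 down; adjusted p = 0.20) did not pass as groups.

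Markers of other cell types moved with total pre-DC. Of 15 measured macrophage genes, 14 rose and none fell (15 adjusted over the list alone; adjusted p = 1.4e-16). Their mean level was 9.66 ± 0.10 in total pre-DC, 5.67 ± 0.13 in CDP and between 6.13 and 6.41 in the 4 pre-DC subsets. Where all 3 arrays of a population were below detection, the fold is a lower bound, the mean of the brighter population against the lowest signal among detected probes. On that rule the complement gene C1qb was at least 39.0-fold higher in total pre-DC (adjusted p = 4.0e-08) and C1qc at least 27.4-fold (adjusted p = 4.4e-10). All 7 basophil, mast cell and eosinophil genes rose, 7 also over the list alone (adjusted p = 1.5e-06), with the basophil protease Prss34 at least 19.8-fold higher. Monocyte genes rose in 13 of 17, with 13 adjusted over the list alone (adjusted p = 1.2e-07), led by Fn1 (3.27 ± 0.22). Erythroid genes were up in 8 of 12 and down in 1, also over the list alone (adjusted p = 0.00037; adjusted p = 0.12 with an estimated correlation), and Hbb-bs rose by 3.01 ± 0.27.

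In all, 2024 genes rose and 2528 fell in total pre-DC against CDP, 952 of them by at least 2-fold. With the mean of the 4 subsets in place of total pre-DC, an alternative chosen after these markers were seen, 5741 genes passed. Of these, 3629 were called in the same direction in total pre-DC and 127 in the opposite direction. Vcam1 then rose by 2.04 in place of 6.99, Slc40a1 by 2.14 in place of 6.50, Fcna by 1.80 in place of 6.08 and Fn1 by 0.41 in place of 3.27. The values for Clec4a1 (1.77), Ifit3 (1.25), Hbb-bs (1.97), C1qb (1.16) and C1qc (0.86) were smaller too, and Prss34 no longer passed (0.20, adjusted p = 0.28, range over all alternatives 1.4e-20 to 0.28). C1qb, C1qc and Prss34 were below detection in CDP, so background sets part of these values and they are not exact. In turn H2-Eb1 (5.20), Spib (3.12) and Cd34 (-2.78) moved further. The macrophage list still passed as higher than CDP (8 up, 0 down), with a median of 0.54 in place of 3.91. The erythroid list did too (7 up, 1 down). Their camera tests gave adjusted p = 0.022 and 0.021, adjusted over the lists of the contrasts with total pre-DC replaced. The monocyte list no longer passed (adjusted p = 0.51, range over all alternatives 9.3e-12 to 0.51). The basophil list turned direction without passing (adjusted p = 0.80, range 8.9e-14 to 0.80). The type 1 list had 17 of 20 genes up and 1 down, against 8 and 1 in total pre-DC, and passed again (adjusted p over all alternatives 8.2e-10 to 0.082). The plasmacytoid DC list then passed as higher (17 up, 1 down; adjusted p = 2.6e-06, range 2.6e-06 to 0.81) and the cell cycle list as lower (2 up, 19 down; adjusted p = 0.0017, range 0.0017 to 0.69). Irf8 (0.50, adjusted p = 0.0047, range 0.0047 to 0.69), Id2 (0.78, adjusted p = 0.00024, range 2.0e-05 to 0.28) and Tcf4 (1.15, adjusted p = 4.5e-06, range 4.5e-06 to 0.97) also passed as higher. That mean weighs the 4 subsets equally, whatever their abundance, which bears on genes and lists that differ with Siglec-H. The calls of Irf8 and Tcf4 thus differ between total pre-DC and an equally weighted mean, and that of Id2 also depends on the probe. With median scaling in place of quantile normalization, 2923 genes passed.

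**Figure D1:**
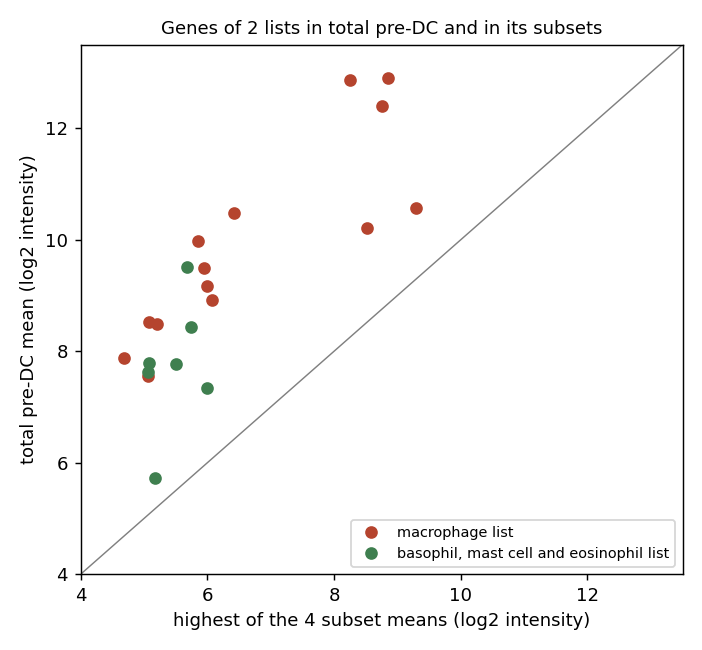
Mean log2 intensity of 21 macrophage and basophil list genes called higher in total pre-DC than in CDP, in total pre-DC (vertical axis) against the highest of the 4 pre-DC subset means (horizontal axis), with the line of equality. All 21 genes lie above the line, 20 of them by at least 2-fold.

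CD8a+ and CD11b+ splenic DC were compared to define the mature expression patterns against which the progenitors could be read. CD8a+ DC held far more mRNA of Irf8 (5.20 ± 0.18, adjusted p = 2.3e-15), a transcription factor needed for type 1 conventional DC, and of the integrin gene Itgae (6.66 ± 0.21, adjusted p = 6.2e-16). The same held for Ifi205 (7.01 ± 0.19) and Clec9a, a receptor for dead cells (4.67 ± 0.11). The endosomal gene Rab7b was at least 101-fold higher (adjusted p = 7.5e-21), the chemokine receptor gene Xcr1 at least 18.6-fold (adjusted p = 3.7e-18), and Tlr3, a sensor of double-stranded RNA, at least 8.52-fold (adjusted p = 1.2e-15). CD11b+ DC held more Sirpa (-4.30 ± 0.15), Csf1r (-3.40 ± 0.22), Irf4 (-2.47 ± 0.27), Klf4 (-2.61 ± 0.17), Zeb2 (-3.22 ± 0.24) and Dtx1, a Notch target (-6.30 ± 0.19, adjusted p = 3.7e-16), where a negative value is lower in CD8a+ DC. The lectin genes Clec4a1 and Clec4a4 were at least 47.9-fold and at least 31.5-fold higher in CD11b+ DC (adjusted p = 1.2e-15 and 4.1e-19).

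All 20 conventional DC type 1 genes were higher in CD8a+ DC (20 adjusted over the list alone; adjusted p = 2.0e-20). In turn, 20 of 21 type 2 genes were higher in CD11b+ DC, with 1 the other way (20 and 1 adjusted over the list alone; adjusted p = 1.1e-14). Interferon response genes were lower in CD8a+ DC in 15 of 24 and higher in 6 (15 and 7 adjusted over the list alone; adjusted p = 0.0017; adjusted p = 0.14 with an estimated correlation), with Ifit3 at -4.97 ± 0.13. C-type lectin receptors (12 lower, 4 higher; adjusted p = 0.0046, or adjusted p = 0.11 with an estimated correlation) and monocyte genes (9 lower, 1 higher; adjusted p = 0.0068, or adjusted p = 0.26 with an estimated correlation) also stood lower as groups, with the same counts over the lists alone. Immediate early and stress genes were lower in 11 of 22 (12 lower and 1 higher adjusted over the list alone; adjusted p = 0.0019; adjusted p = 0.40 with an estimated correlation). Haemoglobin genes such as Hbb-bs were higher in CD8a+ DC (3.01 ± 0.27), although the erythroid list did not pass (4 up, 2 down of 12, with 5 and 2 adjusted over the list alone; adjusted p = 0.37). The test called 2549 genes higher and 2340 lower in CD8a+ DC, 1335 of them by at least 2-fold. Median scaling called 2691 genes and moved the share called higher from 52.1% to 39.6%.

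Among pre-DC without Siglec-H, Ly6C+ cells were set against Ly6C- cells to ask whether these subsets already differ along the lines of the splenic DC. Ly6C-Siglec-H- pre-DC held more Id2 (difference -2.92 ± 0.20, adjusted p = 1.1e-09) and Batf3 (-2.08 ± 0.10, adjusted p = 9.4e-12), transcription factors of type 1 conventional DC. They also held more Kit (-2.86 ± 0.11, adjusted p = 4.3e-13) and more Il12a (-3.69 ± 0.11), a subunit of interleukin 12. The germinal centre gene Gcsam was at least 7.79-fold and Dntt at least 21.8-fold higher in them (adjusted p = 8.6e-14 and 1.2e-13). Ly6C+Siglec-H- pre-DC held more mRNA of the monocyte genes Fn1 (3.81 ± 0.22, adjusted p = 7.2e-11) and F13a1 (3.39 ± 0.14, adjusted p = 8.8e-13), of Csf1r, the receptor for macrophage colony stimulating factor (2.19 ± 0.22). Their Irf4 (1.31 ± 0.27), Klf4 (1.19 ± 0.17) and Zeb2 (1.28 ± 0.24) were higher too. Irf8 was lower in the Ly6C+ cells (-0.72 ± 0.18, adjusted p = 0.0054), a call that ended under median scaling, while Tcf4 did not pass (-0.08 ± 0.21, adjusted p = 0.85).

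Of 20 conventional DC type 1 genes, 17 were lower in Ly6C+Siglec-H- pre-DC and none higher, also over the list alone (adjusted p = 2.3e-18). Their mean level was 7.02 ± 0.05 there, 8.57 ± 0.03 in Ly6C-Siglec-H- pre-DC and 10.82 ± 0.02 in CD8a+ splenic DC. Of 21 type 2 genes, 12 were higher and 1 lower (12 and 3 adjusted over the list alone; adjusted p = 0.00037; adjusted p = 0.085 with an estimated correlation), among them Cd7 (1.56 ± 0.21). Monocyte genes moved with the Ly6C+ cells: 12 of 17 were higher and 1 lower (13 and 1 adjusted over the list alone; adjusted p = 3.0e-09). Stem and progenitor genes were lower in 12 of 21 and higher in 1 (13 and 2 adjusted over the list alone; adjusted p = 2.9e-06), with Egfl7 at -2.04 ± 0.10. Of 14 MHC class II pathway genes, 8 were lower and 2 higher (8 and 4 adjusted over the list alone; adjusted p = 0.0017; adjusted p = 0.18 with an estimated correlation), with H2-Ob at -2.34 ± 0.14. B cell genes were lower in 4 of 11, also over the list alone (adjusted p = 0.0020; adjusted p = 0.28 with an estimated correlation), with the kinase gene Blk at least 13.4-fold lower (adjusted p = 7.4e-11), although 1 of its 2 other detected probes did not pass (-0.32, adjusted p = 0.057).

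The test called 1026 genes higher and 1152 lower in Ly6C+Siglec-H- pre-DC, 421 by at least 2-fold, and 994 in all under median scaling. Arrays of these subsets with the same replicate number deviated together. With that number as a block, Spib (0.52 ± 0.17, adjusted p = 0.038), whose call also ended without any single array of the 6, no longer passed (adjusted p = 0.052, range over all alternatives 0.00075 to 0.12). The DC maturation list, 5 of 15 lower and 2 higher (6 and 2 adjusted over the list alone; adjusted p = 0.054), passed as lower (adjusted p = 0.045, range 0.0033 to 0.38).

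The same comparison within Siglec-H+ pre-DC asked whether Ly6C marks the same difference there. Ly6C+Siglec-H+ pre-DC held more Klf4 (2.21 ± 0.17, adjusted p = 8.5e-09) and Irf4 (1.92 ± 0.27, adjusted p = 3.0e-05). They also held more mRNA of the lectin genes Cd209d (3.20 ± 0.65) and Cd209e (2.89 ± 0.16), and more F13a1 (2.77 ± 0.14) and Ccr2, a chemokine receptor of monocytes (2.58 ± 0.11, adjusted p = 8.5e-12). Ly6C-Siglec-H+ pre-DC held more Id2 (-1.99 ± 0.20, adjusted p = 2.7e-07), Batf3 (-1.18 ± 0.10, adjusted p = 4.7e-08), Arpp21 (-2.69 ± 0.19) and Blk (-2.29 ± 0.24), a kinase of B cells. Of the other detected probes, 1 of 2 for Id2 (-0.19, adjusted p = 0.46) and the 1 for Batf3 (-0.12, adjusted p = 0.70) did not pass, and the Batf3 probe used was detected on 1 of 3 Ly6C+Siglec-H+ arrays. Clec9a (1.43 ± 0.11, adjusted p = 1.1e-08) and Btla (1.49 ± 0.09) were higher in the Ly6C+ cells. Those type 1 genes thus went against Rab7b (-1.31 ± 0.11) and Itgae, which was at least 2.05-fold lower (adjusted p = 0.00012). Irf8 (-0.15 ± 0.18, adjusted p = 0.68), Tcf4 (-0.15 ± 0.21, adjusted p = 0.73) and Zeb2 (-0.02 ± 0.24, adjusted p = 0.98) did not pass.

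Conventional DC type 1 genes were lower in 7 of 20 and higher in 3 (8 and 3 adjusted over the list alone; adjusted p = 0.037; adjusted p = 0.19 with an estimated correlation). Leaving out either Ly6C+Siglec-H+ replicate 3 or Ly6C-Siglec-H+ replicate 3 ended that call. Type 2 genes were higher in 8 of 21 and lower in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.00047; adjusted p = 0.090 with an estimated correlation). Monocyte genes were higher in 9 of 17, also over the list alone (adjusted p = 2.4e-06; adjusted p = 0.059 with an estimated correlation). Stem and progenitor genes were lower in 9 of 21 (10 lower and 1 higher adjusted over the list alone; adjusted p = 0.015), among them Egfl7 (-1.06 ± 0.10) and Cd93 (-0.82 ± 0.17). Neutrophil and granule genes were higher in 6 of 16 (7 adjusted over the list alone; adjusted p = 0.0053; adjusted p = 0.18 with an estimated correlation), with S100a8 at 1.31 ± 0.25. The test called 975 genes higher and 1061 lower, 300 by at least 2-fold. Median scaling called 855 genes and moved the share called higher from 47.9% to 65.5%.

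**Figure D2:**
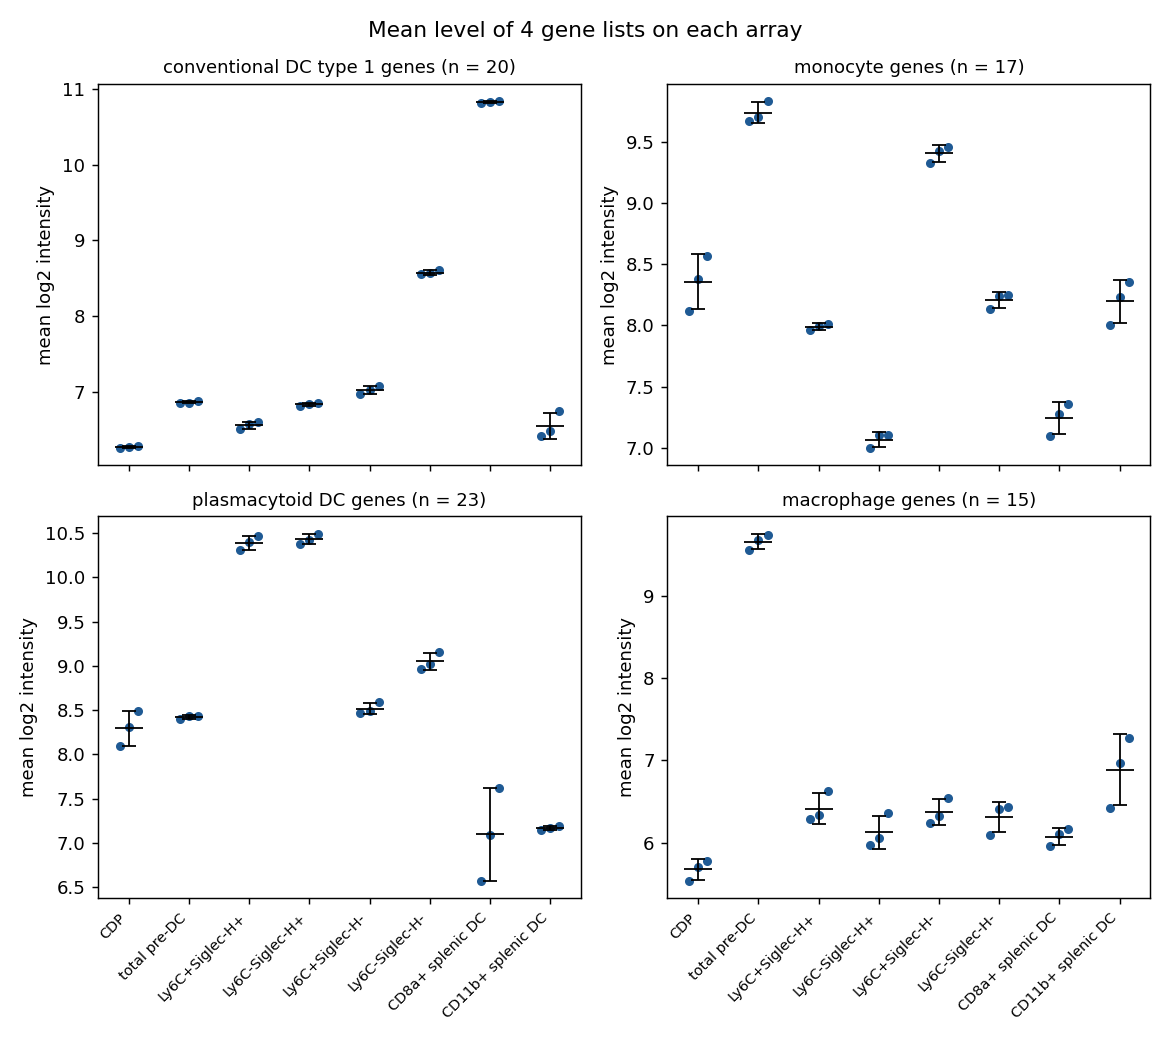
Mean log2 intensity of the conventional DC type 1, monocyte, plasmacytoid DC and macrophage lists (vertical axes) on each array of the 8 populations (horizontal axes); points are arrays and bars are the mean ± SD of 3 arrays. The type 1 list stands highest among the pre-DC subsets in Ly6C-Siglec-H- cells (8.57), the plasmacytoid list in both Siglec-H+ subsets (10.39 and 10.43), and the macrophage list in total pre-DC (9.66).

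To set the progenitor subsets against the splenic DC gene by gene, the difference between CD8a+ and CD11b+ DC was correlated across 10317 genes with the difference between Ly6C- and Ly6C+ pre-DC. Genes are not independent replicates. Among Siglec-H- pre-DC the genes higher in Ly6C- cells tended to be those higher in CD8a+ DC (Pearson r = 0.212, Spearman rho = 0.166), and 2 of 100 paired splits of the arrays gave a correlation as large, the real split included. The other split gave 0.214, above the real one, and mixed the populations, with both Siglec-H- arrays of replicate 1 on the same side. The splits took no account of the deviations shared by arrays with the same replicate number. The share was 0.06 to 0.08 under 6 of the alternatives tried, and 0.01 to 0.04 under the others for which splits were taken. Of 1365 genes called in both comparisons, 947 (69.4%) moved in the matching sense. Of these, 493 were higher in CD8a+ DC and Ly6C- pre-DC, where 284.6 would be shared by independent lists, and 454 in CD11b+ DC and Ly6C+ pre-DC, where 232.7 would be. Among Siglec-H+ pre-DC the correlation was 0.0233 (Spearman rho = 0.0055), 33 of 100 splits gave one as large, and 620 of 1229 genes (50.4%) moved in the matching sense.

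A splenic score was then taken on the bone marrow arrays. It was the mean log2 intensity of the 100 genes highest in CD8a+ DC minus that of the 100 genes highest in CD11b+ DC. These genes were ranked by the difference between the splenic arrays. Bone marrow arrays entered the choice only through the common spread, the detection filter and the probe used. The splenic arrays themselves scored 3.93 ± 0.32 for CD8a+ DC and -4.18 ± 0.16 for CD11b+ DC (SD, n = 3). Ly6C-Siglec-H- pre-DC scored 0.594 ± 0.069 (SD, n = 3) and Ly6C+Siglec-H- pre-DC -0.386 ± 0.020, a difference of 0.980. Ly6C-Siglec-H+ pre-DC scored 0.182 ± 0.018 and Ly6C+Siglec-H+ pre-DC -0.0011 ± 0.0069, a difference of 0.183. The exact permutation test, two-sided, gave p = 0.1 for each pair (n = 3 a group), the smallest p that 3 arrays against 3 allow. Of the 100 CD8a-high genes, 57 were lower and 4 higher in Ly6C+Siglec-H- than in Ly6C-Siglec-H- pre-DC (camera, adjusted p = 8.0e-20). Of the 100 CD11b-high genes 42 were higher and 15 lower (adjusted p = 0.00038; adjusted p = 0.30 with an estimated correlation). Among Siglec-H+ pre-DC the CD8a-high genes did not pass, with 19 higher and 15 lower in Ly6C+ cells (camera, adjusted p = 0.65). There 24 CD11b-high genes were higher and 11 lower (camera, adjusted p = 0.0018, or adjusted p = 0.33 with an estimated correlation). Without background correction the differences were 0.639 and 0.0315, and without CD8a+ splenic DC replicate 2 the difference between the Siglec-H+ subsets was 0.107.

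**Figure D3:**
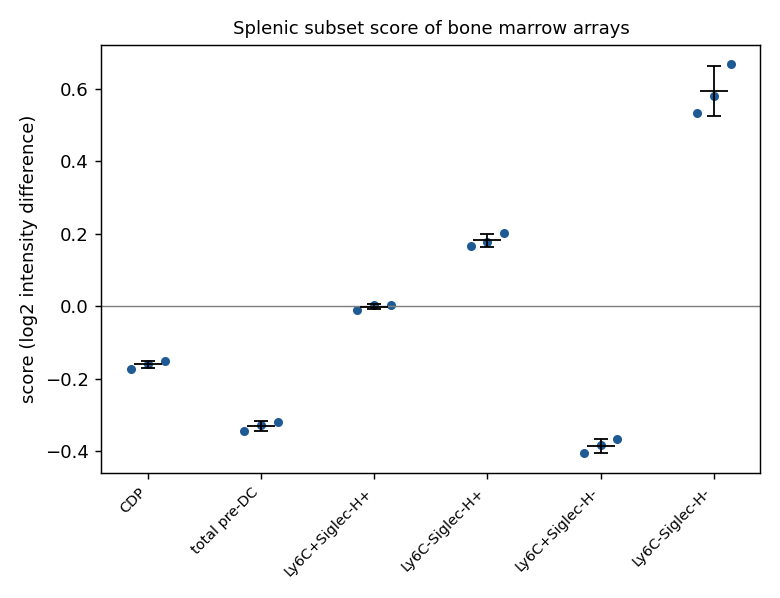
Splenic score (mean log2 intensity of 100 CD8a-high genes minus that of 100 CD11b-high genes, vertical axis) of each of the 18 bone marrow arrays in 6 populations (horizontal axis); points are arrays and bars are the mean ± SD of 3 arrays. Ly6C-Siglec-H- pre-DC stand highest (0.594) and Ly6C+Siglec-H- pre-DC lowest (-0.386).

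Siglec-H+ pre-DC were compared with Siglec-H- pre-DC over both Ly6C states to ask which genes go with Siglec-H, a marker of plasmacytoid DC. Genes known from plasmacytoid DC and early lymphoid cells were higher with Siglec-H: Ly6d by 3.41 ± 0.22 (adjusted p = 6.3e-11), Pacsin1 by 3.31 ± 0.21 (adjusted p = 5.3e-11), Cox6a2 by 3.19 ± 0.22 and Il7r, the interleukin 7 receptor, by 3.01 ± 0.25. The transcription factors Spib (1.79 ± 0.12), Tcf4 (1.57 ± 0.15, adjusted p = 1.7e-08) and Irf8 (0.87 ± 0.13, adjusted p = 9.8e-06) were higher too. Of the other detected probes, 1 of 3 for Pacsin1 (-0.13, adjusted p = 0.51) and 1 of 2 for Tcf4 (0.27, adjusted p = 0.087) did not pass. Tlr7, a sensor of single-stranded RNA, was higher by 2.53 ± 0.10. The Toll-like receptor list went the other way as a group, with 8 of 15 lower and 3 higher (8 and 4 adjusted over the list alone). Its camera test gave adjusted p = 0.017, and adjusted p = 0.17 with an estimated correlation. Batf3 fell by 3.89 ± 0.07 on the log2 scale (adjusted p = 1.7e-18), Id2 by -2.97 ± 0.14, Irf4 by -1.50 ± 0.19, and the MHC class II genes H2-Eb1 and H2-Ab1 by -3.55 ± 0.12 and -3.40 ± 0.09.

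Of 23 plasmacytoid DC genes, 18 were higher and 1 lower (21 and 1 adjusted over the list alone; adjusted p = 3.7e-10; adjusted p = 0.053 with an estimated correlation). The list stood at 10.39 ± 0.08 and 10.43 ± 0.06 in the Siglec-H+ subsets against 8.52 ± 0.06 and 9.05 ± 0.10 in the Siglec-H- subsets. MHC class II pathway genes were lower in 11 of 14 and higher in 1 (12 and 1 adjusted over the list alone; adjusted p = 2.6e-09), and type 1 genes lower in 14 of 20 and higher in 2, also over the list alone (adjusted p = 1.3e-07). Cell cycle genes were higher in 23 of 34 (24 adjusted over the list alone; adjusted p = 8.2e-07; adjusted p = 0.15 with an estimated correlation), by a median of 0.38, with E2f1 at 0.76 ± 0.05. Monocyte genes were lower in 13 of 17 and higher in 2, also over the list alone (adjusted p = 4.1e-06; adjusted p = 0.065 with an estimated correlation), with Lyz2 at -3.38 ± 0.18. Type 2 genes (12 lower and 4 higher of 21; adjusted p = 0.00070, or adjusted p = 0.096 with an estimated correlation) were lower as a group, and B cell genes (7 higher and 1 lower of 11; adjusted p = 0.0071, or adjusted p = 0.34 with an estimated correlation) higher, with the same counts over the lists alone. Blk was higher by 2.93 ± 0.17. Immediate early and stress genes were lower in 14 of 22 and higher in 2, also over the list alone (adjusted p = 0.0012; adjusted p = 0.38 with an estimated correlation), with Junb at -1.66 ± 0.12. The test called 2256 genes higher and 1995 lower, 661 by at least 2-fold. Median scaling called 2814 genes and moved the share called higher from 53.1% to 64.2%.

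Whether Ly6C marks a different change with and without Siglec-H was tested directly by the interaction, in which a positive value means a Ly6C effect that is higher, or less negative, in Siglec-H+ cells. Kit, the stem cell factor receptor, was lower with Ly6C by -2.86 in Siglec-H- pre-DC and by -0.43 in Siglec-H+ pre-DC (interaction 2.43 ± 0.16, adjusted p = 6.0e-09). Another Kit probe gave -0.19 in Siglec-H+ pre-DC (adjusted p = 0.34), but was below detection on all arrays there and cannot check that value. Septin3 was lower by -2.87 without Siglec-H and stood at 0.02 with it (2.89 ± 0.25, adjusted p = 1.5e-07; 1 of 3 other probes 0.63, adjusted p = 0.24), and Ffar4, a fatty acid receptor gene, turned from -1.58 to 1.91 (3.50 ± 0.17, adjusted p = 8.8e-11). Sirpa rose with Ly6C by 1.34 without Siglec-H and did not change with it (interaction -1.35 ± 0.21, adjusted p = 0.00021), although its other detected probe did not pass (-0.49, adjusted p = 0.35). That other probe was below detection on all Ly6C-Siglec-H- arrays, which limits what it could show. Tnfaip2, a gene induced by tumour necrosis factor, rose with Ly6C by 1.98 without Siglec-H and stood at 0.04 with it (-1.93 ± 0.32, adjusted p = 0.00047). Each of these genes was detected on all arrays of the 4 subsets with the probe used here.

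Of 20 type 1 genes, 14 had a positive interaction and none a negative one (18 adjusted over the list alone; adjusted p = 7.0e-26), and 7 of these 14 were detected on all 6 Siglec-H+ arrays. MHC class II pathway genes (6 of 14 positive, 7 adjusted over the list alone; adjusted p = 6.0e-09), Toll-like receptors (5 of 15, 5 adjusted over the list alone; adjusted p = 2.1e-05) and stem and progenitor genes (4 of 21, with 4 positive and 1 negative adjusted over the list alone; adjusted p = 0.00054) were also positive as groups. Cell cycle genes had a negative interaction in 4 of 34 (10 adjusted over the list alone; adjusted p = 1.1e-08; adjusted p = 0.094 with an estimated correlation), with a median of -0.27. Of the 100 CD8a-high genes, 40 had a positive interaction and none a negative one (adjusted p = 2.2e-33). The 100 CD11b-high genes did not pass (adjusted p = 0.77). The test called 446 genes positive and 198 negative, 226 of them by at least 2-fold. As many were called by 9 of 100 regroupings of the 12 arrays, the real one included, and by 1 of 100 when the additive effects of Ly6C and Siglec-H were removed first, a test added after the result was seen. Median scaling called 258 genes, 84.1% of them positive against 69.3%, and array weights called 1005.

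Splenic DC of both subsets were compared with total pre-DC to ask what differs between progenitors and mature cells. Organ, and the set in which the arrays were processed, differ in the same way and cannot be told apart from maturity. H2-Eb1 was higher in splenic DC by 6.29 ± 0.14 (adjusted p = 1.7e-18), Cd83, a marker of mature DC, by 5.64 ± 0.12, Batf3 by 3.64 ± 0.09 and Id2 by 3.44 ± 0.17. The nuclease gene Dnase1l3 was at least 251-fold and Il1b, for interleukin 1 beta, at least 163-fold higher (adjusted p = 1.4e-22 and 9.8e-21). Klf4 (-2.77 ± 0.15), Irf8 (-1.70 ± 0.15) and Ly6c1 (-6.52 ± 0.29) were lower, and the granule gene Mpo was at least 143-fold lower (adjusted p = 1.1e-17). All these values are for the mean of CD8a+ and CD11b+ DC. Irf8 was far higher in CD8a+ than in CD11b+ DC, so its mean describes neither subset. Tcf4 was lower by -1.55 ± 0.18 with the probe used here, and its other 2 detected probes showed no call (-0.02, adjusted p = 0.88, and 0.01, adjusted p = 0.94). Sirpa was lower by -1.16 ± 0.13 with the probe used here and higher by 0.99 with its other detected probe. That other probe was below detection on all CD8a+ arrays, so background sets part of its value and its direction is not secure. With the probe used here Sirpa stood at 12.62 in total pre-DC, 13.61 in CD11b+ DC and 9.31 in CD8a+ DC. The mean of the splenic subsets thus hides opposite directions. With the 4 subsets in place of total pre-DC, H2-Eb1 was higher by 3.93 and Mpo lower by -3.98, both smaller, and Tcf4 lower by -2.80 and Sirpa by -0.51. The immediate early genes Egr2 and Egr3 were at least 22.3-fold and at least 35.6-fold higher in splenic DC (adjusted p = 1.2e-16 and 3.1e-17).

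All 15 DC maturation genes were higher in splenic DC, also over the list alone (adjusted p = 2.6e-09). So were 13 of 14 MHC class II pathway genes, with 1 lower (13 and 1 adjusted over the list alone; adjusted p = 2.9e-08), and 17 of 20 type 1 genes, with 2 lower (17 and 2 adjusted over the list alone; adjusted p = 1.3e-07). For the type 1 list the rise was that of CD8a+ DC. Its mean level was 10.82 in CD8a+ DC, 6.55 in CD11b+ DC and 6.87 in total pre-DC. All 34 cell cycle genes were lower, also over the list alone (adjusted p = 1.1e-09; adjusted p = 0.079 with an estimated correlation), by a median of -1.20, with Birc5 at -2.08 ± 0.07. Immediate early and stress genes were higher in 19 of 22 and lower in 1, also over the list alone (adjusted p = 1.3e-07; adjusted p = 0.16 with an estimated correlation). Macrophage genes moved with total pre-DC here too: all 15 were lower in splenic DC, also over the list alone (adjusted p = 2.1e-05; adjusted p = 0.13 with an estimated correlation). That direction turned, without passing, when the 4 subsets took the place of total pre-DC. T cell and NK cell genes (3 up and 3 down of 8; adjusted p = 0.99) and chemokine and homing receptors (7 up and 8 down of 15; adjusted p = 0.79) did not pass as groups. The test called 3068 genes higher and 4751 lower, 2770 by at least 2-fold, around a median of -0.17 over all genes. Median scaling, which moved that median to -0.81, lowered the share called higher from 39.2% to 12.8%, so sizes in this comparison are relative to the scaling.

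Over the 7 comparisons, 72 list tests passed, and 24 of these held with an estimated correlation between genes. Those that did not are given with that p where they are described here.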

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

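The tests of total pre-DC and CDP against the 4 subsets, of the detection floor, of the level that a share of mature DC would bring, and of the interaction with additive effects removed were chosen only after the result was seen. The other tests of the 3 patterns weighed here were written after the first fits but before their own results, and the contrasts and gene lists were chosen before the data were examined.

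A difference between groups was found for the effect of Ly6C in pre-DC with and without Siglec-H, tested as an interaction. At the threshold 644 genes passed. The genes named by size with a positive interaction were Ffar4 (3.50), Gcsam (3.00), Septin3 (2.89), Snx22 (2.77) and Dntt (2.72), and those with a negative one were Fcgr1 (-2.21), Tnfaip2 (-1.93), Lilrb4a (-1.88), Papss2 (-1.84) and Cdkn1a (-1.67). Of these, Gcsam, Snx22, Dntt, Fcgr1, Lilrb4a and Papss2 were not detected on all arrays of the 4 subsets, so the detection floor sets part of their values and of their order. Among sorting markers and transcription factors, Csf1r (-1.20), Il7r (2.25), Kit (2.43), Sirpa (-1.35), Batf3 (0.90), Klf4 (1.03), Spib (-0.83) and Zeb2 (-1.30) passed, with Batf3 detected on 1 of 3 Ly6C+Siglec-H+ arrays. Id2 did not pass with the probe used, where its Ly6C effect was -2.92 without and -1.99 with Siglec-H. Its other detected probes gave -2.33 and -2.75 without Siglec-H, and -0.19 and -0.99 with it. With at least 1 other detected probe the interaction did not pass for Sirpa (-0.49, adjusted p = 0.35), Septin3 (0.63, adjusted p = 0.24), Snx22 (0.38, adjusted p = 0.59), Papss2 (-0.48, adjusted p = 0.35), Cdkn1a (-0.21, adjusted p = 0.83), Il7r (3 probes, adjusted p = 0.17 to 0.98), Klf4 (2 probes, 0.18 and 0.51) and Zeb2 (2 probes, 0.077 and 0.22). These Il7r probes were below detection on all Ly6C+Siglec-H- arrays, and this Sirpa probe on all Ly6C-Siglec-H- arrays. The floor limits the interaction that they could show. Leaving out any of several single arrays ended the calls of Lilrb4a, Papss2, Csf1r, Spib and Zeb2 and of the DC maturation list. The mean of a gene's probes ended those of Il7r and Klf4, and median scaling that of Batf3. The lists that passed were the type 1 conventional DC genes (adjusted p = 7.0e-26), MHC class II pathway (6.0e-09), cell cycle (1.1e-08), Toll-like receptors (2.1e-05), stem and progenitor (0.00054), plasmacytoid DC (0.0081), B cell (0.020), basophil, mast cell and eosinophil (0.020) and DC maturation genes (0.033). With an estimated correlation the cell cycle, plasmacytoid DC, B cell, basophil and DC maturation lists did not pass (adjusted p = 0.094, 0.39, 0.40, 0.12 and 0.33).

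The first pattern weighed was the lower level of type 1 conventional DC genes with Ly6C, larger in Siglec-H- than in Siglec-H+ pre-DC. A background floor in Siglec-H+ cells was argued against for the 11 list genes detected on all 12 subset arrays (median interaction 1.28, all 11 above 0), but stays open for others, since only 7 of the 14 genes that passed were detected on all 6 Siglec-H+ arrays. For mature CD8a+ DC among Ly6C-Siglec-H- cells, 100 other genes highest in CD8a+ DC implied a median share of 1.46% of such RNA (quartiles 0.236 to 4.64), and 18 type 1 genes implied 10.5% (1.54 to 34.0), with overlapping quartiles. A share of 10.5% with the splenic profile, as the cause of the whole pattern, was argued against, since 6 of 21 genes bright enough to show it stood over 10-fold below the level it would bring; 2 bars set earlier were not met (25 of the 100 genes, more than could show it, and an upper quartile of the log2 differences below 0, at 0.0944, which a gene's own expression can raise). A smaller share, for genes that need little, and a biological difference between the subsets stay open.

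The second pattern was the rise of macrophage and basophil genes in total pre-DC, where all 21 genes called lay above all 4 subsets and 20 did so by at least 2-fold. A mixture of the 4 subsets was argued against by the median excess over the highest subset, a log2 of 3.17. Normalization together with spleen was argued against by the same excess in the deposited processed values (2.16). Those bone marrow values also shared the same distribution, so the test cannot weigh quantile normalization itself. For an array batch shared with CDP, the CDP excess over the highest subset was a median log2 of -0.44 (quartiles -1.04 to -0.13) over all 22 measured genes of the 2 lists, called or not. This test cannot decide, since the highest of 4 means pulls the excess down and 21 of the 22 genes were called lower in CDP than in total pre-DC. Genes below detection in CDP, C1qb and C1qc among them, could hardly show a batch effect. Other cells in the total pre-DC sort, which would raise all 15 of 15 macrophage genes as seen, cannot be told apart from pre-DC that lie outside the 4 subsets.

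The third pattern was the number of calls when the arrays were regrouped. For the Siglec-H contrast 1 of 100 regroupings called as many genes, the real one (4251, highest other 2407). For splenic DC against total pre-DC 1 of 84 did (7819, highest other 6680). Both shares argue against a chance division of these arrays into their populations, and say no more than that. The regroupings mixed populations that also differ by Ly6C or by splenic subset. Such mixing widens the spread within groups and lowers the number of calls. Variation between mice could not be weighed by regrouping, since the labels do not say that replicates came from separate mice. For the interaction 9 of 100 regroupings called as many as the real 644 (highest other 2403), which by itself does not exclude chance; all 8 others placed Siglec-H or Ly6C unevenly and so carried its effect into the interaction, a structure of the samples. With these additive effects removed before regrouping, 1 of 100 called as many, the real one (highest other 64). That test, added after the result was seen, argues against a chance division of these arrays. For total pre-DC against CDP (highest other 1), the splenic subsets (363), and Ly6C without (0) and with Siglec-H (1), 1 of 10 splits called as many, and 10 splits are too few for a share under 0.05.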

How the results depend on the processing

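The test with the 4 subsets in place of total pre-DC, and that with separate normalization of the organs, were chosen only after the result was seen. Over all alternatives, named genes kept their side of the threshold in 8390 comparisons, lost the call in 230, gained it in 38 and turned with a call in 25, where turns with no call on either side count as kept; when arrays were left out, 5039 kept it, 274 lost it, 12 gained it and 0 turned. Lists kept it in 1916 comparisons, lost it in 80, gained it in 88 and turned in 6, and without single arrays in 1050, 17, 16 and 0. Without single arrays the counts stayed within 4055 to 4183 for total pre-DC against CDP, 4512 to 4840 for the splenic subsets, 1717 to 1974 and 1567 to 1698 for Ly6C without and with Siglec-H, 3979 to 4125 for Siglec-H, 504 to 573 for the interaction, 7378 to 7875 for splenic DC against total pre-DC and 67 to 76 for the lists; agreement stayed within 0.202 to 0.222 and 0.0153 to 0.0307, and score differences within 0.821 to 1.03 and 0.107 to 0.216. The lowest score difference (0.107) and agreement (0.0153) with Siglec-H came without CD8a+ splenic DC replicate 2. Signal over background limits the folds of dim genes, given as lower bounds.

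Values that moved by over 1.5 times or crossed a threshold follow, with score differences that moved by more than the pooled SD of their arrays. The list count of fry did not move that far and is given beside them. The cause was not tested. Median scaling called 2923, 2691, 994, 855, 2814 and 258 genes in the first 6 contrasts, and moved the median of all genes to -0.13 for total pre-DC and -0.81 for splenic DC against total pre-DC (-0.11 without background correction). Score differences without and with Siglec-H were 0.639 and 0.0315 without background correction, 0.706 and 0.0366 with the authors' values, 0.773 and 0.0822 with the mean of probes, 1.11 and 0.222 with 50 genes, and 0.683 and 0.0648 with 200 genes. Every probe tested separately, more features by construction, called 7045 for total pre-DC, 8146 for the splenic subsets, 6795 for Siglec-H and 14270 for splenic DC against total pre-DC, with a score difference of 1.09. Array weights called 1005 genes for the interaction. Stricter thresholds call fewer by construction: 952, 1335, 421, 300, 661, 226 and 2770 at 2-fold, and 1252 (Ly6C with Siglec-H) and 343 (interaction) at an adjusted p of 0.01. An estimated correlation kept 24 lists, and fry called 102. The agreement without Siglec-H was 0.233 without background correction, 0.209 with median scaling, 0.228 with the authors' values and 0.283 over splenic-called genes (share of splits 0.08 each), 0.217 with a detection p under 0.01 (0.06) and 0.205 with every probe (0.07). That with Siglec-H was 0.0133 without background correction and 0.0123 with every probe.

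Directions turned for splenic DC against total pre-DC in Cebpe (-0.38 without background correction, -0.79 with median scaling, -0.77 with loess), Irf7 (-0.0323), Tlr7 (-0.32) Klrk1 (-0.37) and Il7r (-0.63) with median scaling, and Clec9a (0.0143) with the mean of probes. With the subsets in place of total pre-DC they turned against CDP in Ly6c1 (-0.23), Cox6a2 (0.27), Gata2 (-0.46), Tfrc (0.38), Egr1 (0.0350), Clec2d (0.0723), Csf1r (-1.30), Siglech (2.03), Irf8 (0.50), Tcf4 (1.15) and the basophil list (direction -1), and against splenic DC in Csf1r (0.24), Tlr7 (-0.0674), Lgmn (0.0495), Fcrla (-1.45), Cd72 (-0.37), Klrd1 (-0.23), Il7r (-2.73) and the macrophage and basophil lists (direction 1 each). With fry the plasmacytoid DC list (direction -1) and the chemokine list (direction 1) turned for the splenic subsets, and the chemokine list (direction -1) for splenic DC against total pre-DC.

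With a replicate block 4484, 4975, 2230, 1915, 4191, 617 and 7809 genes and 74 lists passed. The pairs without Siglec-H are in the report; the block changed no other call there. In the other contrasts of the report the block ended Egfl7 (splenic subsets) and Papss2, Spib, Tk1 and Klrb1b (interaction), and added Tcf4 and the macrophage list (splenic subsets) and Id2 (interaction). Outside those contrasts, CDP and Ly6C-Siglec-H+ arrays with the same number also deviated together (0.118, 0.363 and 0.274); both enter the alternative with the subsets against CDP, for which no block was run. A block by BeadChip was not run, since no source used here gives the chips.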

Other observations

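Every test in this part belongs to the contrasts of the report, so no test here was chosen only after the result was seen. The genes described here and their patterns across populations, however, were picked from their values.

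Some genes stood higher in Ly6C- than in Ly6C+ pre-DC with and without Siglec-H. Dntt, an enzyme of antigen receptor rearrangement, stood at 10.95 ± 0.36 (SD, n = 3) in CDP, 9.68 ± 0.21 in Ly6C-Siglec-H- and 8.88 ± 0.10 in Ly6C-Siglec-H+ pre-DC, against 6.89 ± 0.33 in Ly6C+Siglec-H+ pre-DC and no detection on any of the 3 Ly6C+Siglec-H- arrays. Il12a, for a subunit of interleukin 12, stood at 11.06 ± 0.19 in CDP, 9.85 ± 0.14 and 10.49 ± 0.08 in the Ly6C- subsets without and with Siglec-H, and 6.16 ± 0.26 and 8.79 ± 0.02 in the matching Ly6C+ subsets. The Fc receptor-like gene Fcrla, known from B cells, was high in CD8a+ splenic DC (10.88 ± 0.21), in both Siglec-H+ subsets (10.56 ± 0.24 and 11.19 ± 0.08) and in Ly6C-Siglec-H- pre-DC (9.34 ± 0.07), but low in CDP (6.99 ± 0.32) and Ly6C+Siglec-H- pre-DC (6.34 ± 0.05) and not detected in CD11b+ splenic DC.

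Ngfr, the low-affinity nerve growth factor receptor, was higher in Ly6C+ cells by 2.77 ± 0.17 (SE; adjusted p = 1.7e-10) without Siglec-H and by 2.86 ± 0.17 (adjusted p = 2.3e-10) with it, and the interaction did not pass (0.09, adjusted p = 0.93). Mpo, for the granule enzyme myeloperoxidase, stood at 14.77 ± 0.16 in CDP and 12.93 ± 0.13 in total pre-DC, above all 4 subsets, where it was highest in Ly6C-Siglec-H- pre-DC (10.62 ± 0.17).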
